A study of Mus musculus with 22 samples.

How the data were processed

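RNA-seq libraries of cardiac myocytes from WT and Myh6-Cre Tmem43 heterozygous mice at 4 and 9 months were analysed from the deposited count tables, 1 per age, with 10 and 12 libraries. Per the labels' protocols, total RNA with an RNA integrity number above 8 was depleted of ribosomal RNA, made into libraries with a stranded total RNA kit and sequenced as paired reads of 100 bases. The values are raw counts per gene, deposited by the authors without normalization. Per the submitters' processing notes, the authors used Trim Galore, HISAT2 and featureCounts with the build mm10. Their versions, parameters and annotation release are not given in the sources used here, and neither is whether counting used strand, so reads of overlapping genes on opposite strands could be counted together. Both tables list the same 21950 gene identifiers, and those of the 9-month table are marked as protein-coding, so noncoding RNAs such as Xist are not analysed here. Positions come from GENCODE vM21 on the same assembly and were found for 21886 identifiers. A library named as the first 9-month WT library has an age field of 4 months but the title and table of the 9-month set, and was kept in the 9-month WT group. Pairs of libraries within a group were compared by a chi-square test over genes with at least 20 counts, and the lowest statistic per degree of freedom was 17.1, so no pair agreed within sampling noise and each library was counted as 1 replicate. The smallest library held 21583626 counts, and 1 CPM then corresponds to over 20 counts.

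Genes were kept by filterByExpr (minimum count 10, minimum total 15) and normalized by TMM in edgeR 4.0.16 under R 4.3.3. Each age was fitted alone with genotype as the only factor by glmQLFit, tested by glmQLFTest (2-sided), and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The difference in genotype effect between ages was tested as a contrast in 1 model of all 22 libraries and 4 groups. CPM values were computed within each comparison from TMM-scaled library sizes, and a log2 CPM used a prior count of 2. The log2 fold changes are the Het level over the WT level. A total of 36 gene lists with 697 genes of processes, quality signs and cell types other than ventricular myocytes were tested by camera in limma 3.58.1 on voom values with the preset correlation of 0.01, where at least 5 members were tested, adjusted over the lists. Lymphocyte, neutrophil, erythroid and Y-linked transcripts had fewer tested members at each single age and were not tested there as lists. Some lists share members: 9 of 32 senescence-associated secretory, 5 of 20 TGF-beta and 5 of 18 cardiac stress genes are also in another list. Such lists are therefore not independent of each other. Camera with an estimated correlation and the rotation test fry were alternatives. Fry asks whether the genes of a list move on balance in a direction and does not compare the list with other genes. Genes adjusted over the list alone were adjusted over the tested members of that list.

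The genes named were Tmem43, the 8 highest and 8 lowest log2 fold changes per age among called genes with a mean of at least 1 CPM in the higher group and a symbol that is not a predicted model, up to 4 members by p of each list that passed or had at least 2 called members, and the 5 smallest adjusted p per direction for the difference between ages. Some of the genes that this rule selects, and some found in other ways, are not reported here. Groups, lists, tests, the rule for named genes and most alternatives were chosen before the data were examined. The alternatives were other normalizations (RLE, upper quartile), no filter on low counts or a filter of 1 CPM, the replicate number as a block, mitochondrial genes left out, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma voom with sample weights, all 22 libraries in 1 model, and each library left out in turn. Covariates of the Y-linked, fibroblast-marker and atrial-marker means, and tests within and between libraries with and without Y-linked reads, were added after the data were seen.

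The tests were checked on simulated counts drawn from the means and library sizes of the real libraries with genes changed by known folds. At 4 months, 20.7% of genes changed 1.5-fold, 64.3% of those changed 2-fold and 95.5% of those changed 4-fold were recovered over 12340 genes; at 9 months it was 55.6%, 83.8% and 100% over 12447 genes, and for the difference between ages 5.17%, 51.5% and 86.7% over 13033 genes. False calls were 8.4%, 6.02% and 4.67% of all calls. Each simulated gene varied independently, without the differences between libraries that many genes share in the real data. The rates may therefore not hold for the real libraries. Changes of under 2-fold at 4 months, or in the difference between ages, were thus often not detectable at this depth and number of libraries.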

Results

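Gene expression was measured by RNA-seq in freshly isolated mouse cardiac myocytes carrying a heterozygous, myocyte-specific deletion of Tmem43, which encodes a transmembrane protein of the inner nuclear envelope and endoplasmic reticulum. Deletion was driven by Cre recombinase under the Myh6 promoter, which is active in cardiac myocytes. The labels place 22 libraries in 4 groups: 5 wild-type (WT) and 5 heterozygous (Het) libraries at 4 months of age, and 6 WT and 6 Het libraries at 9 months. The design asked for early transcript changes at 4 months and late ones at 9 months. Wild-type mice carry no Cre according to the labels, so an effect of Cre itself cannot be told apart from that of Tmem43 here. Total counts over 21950 protein-coding genes ranged from 27957374 to 38026915 per library at 4 months and from 21583626 to 29545850 at 9 months. Transcripts of the 13 mitochondrially encoded genes took 32.4% ± 7.08 (SD, n = 5) of counts in WT and 30.9% ± 5.85 (SD, n = 5) in Het libraries at 4 months, and 25.9% ± 6.15 (SD, n = 6) and 23.2% ± 6.16 (SD, n = 6) at 9 months. WT replicate 3 of the 4-month set stood apart, with 12169 genes detected against at least 13639 in every other library of that age. Y-linked transcripts were present in 3 and absent in 2 libraries of each 4-month group, and present in 3 and absent in 3 libraries of each 9-month group. Libraries counted as absent had at most 1 Y-linked count, and those counted as present had at least 4935. The labels do not say that the libraries come from separate animals, so the p-values measure the spread between these libraries.

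Tmem43 (ENSMUSG00000030095; mm10 chromosome 6, 91473703 to 91488463, plus strand) is annotated with 1 protein-coding transcript of 12 exons. Its level was not detectably lower in the libraries labelled Het at either age. At 4 months it was 10.9 ± 2.48 CPM (counts scaled to library size; SD, n = 5) in libraries labelled WT and 8.40 ± 1.59 CPM (SD, n = 5) in libraries labelled Het, a log2 difference of -0.37 ± 0.18 (SE; edgeR adjusted p = 0.596). At 9 months it was 19.97 ± 2.78 CPM (SD, n = 6) and 18.47 ± 1.77 CPM (SD, n = 6), a log2 difference of -0.11 ± 0.10 (SE; edgeR adjusted p = 0.575). The 95% confidence intervals, -0.77 to 0.02 at 4 months and -0.32 to 0.10 at 9 months, both exclude a log2 difference of -1, which is a loss of the reads of a whole allele. The counts sum reads over all exons and the labels do not name the deleted ones, so the reads of a shortened transcript would still be counted. The targeted gene therefore did not check the genotype labels, and WT and Het below mean libraries labelled so.

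At 4 months, 17 of 12519 tested genes differed between libraries labelled Het and WT, with 10 higher and 7 lower in Het (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Genes of potassium channels and metabolism were among them. Kcnj14, an inwardly rectifying potassium channel subunit, rose from 2.82 ± 3.87 to 28.6 ± 7.80 CPM, and all 5 Het libraries lay above all 5 WT libraries. Kcnv2, a modifier subunit of voltage-gated potassium channels, fell by 1.32 ± 0.18 (log2, SE; edgeR adjusted p = 0.0161). Alox5, the 5-lipoxygenase of leukotriene synthesis, fell by 1.34 ± 0.22 and Exoc2, a subunit of the exocyst complex that tethers secretory vesicles, fell by 0.69 ± 0.11. Ndnf, a secreted neurotrophic factor, rose by 1.29 ± 0.22 (log2, SE), Klhdc7a by 1.68 ± 0.30, Esd by 0.84 ± 0.12, the guanylate kinase gene Guk1 by 0.80 ± 0.14 and Jpt1 by 0.79 ± 0.14. Ogdhl, an isoform of the E1 subunit of the 2-oxoglutarate dehydrogenase complex, had the highest fold, 6.15 ± 0.92 (log2, SE; edgeR adjusted p = 0.0206), with 0.325 ± 0.203 CPM in WT and 24.6 ± 23.5 CPM in Het, where 4 of 5 libraries lay above all WT libraries. Klk1b22, one of a family of closely similar kallikrein genes whose reads could be shared, was at 1.45 ± 0.833 CPM in Het and was counted in 1 of 5 WT libraries (edgeR adjusted p = 0.0442). The unadjusted p was under 0.05 for 1077 genes, where 626 are expected by chance. The count was sensitive to single libraries: it was 0 without WT replicate 2 or without Het replicate 1 (843 and 898 genes at an unadjusted p under 0.05). It was 2 without WT replicate 1, 4 without WT replicate 3, WT replicate 4 or Het replicate 5, 6 without Het replicate 3, 8 without WT replicate 5 and 9 without Het replicate 4. Kcnv2 lost its call in 3 of the 10 leave-one-out fits and every other gene named here in 6 to 10 of them (adjusted p up to 0.162). DESeq2 called 102 genes.

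Of 32 gene lists testable at 4 months, 8 passed as higher and 7 as lower in Het (limma camera with a preset correlation, adjusted over the lists). In random regroupings of the same libraries, 2 to 16 lists passed, so some lists pass without the genotype labels. No member of any list passed the gene test over all genes, so the members named here are given as values. Cytosolic ribosomal protein genes had the smallest camera p: 34 of 35 had a positive log2 fold change, with a median of 0.29 (camera adjusted p = 2.5e-09; adjusted p = 0.592 with an estimated correlation). Rpl3 stood at 0.57 ± 0.19 and Rps2 at 0.40 ± 0.16 (log2, SE). Across all genes, the log2 fold change at 4 months had a Spearman correlation of -0.27 with the exonic length of the gene, against 0.0017 at 9 months. Genes are not independent replicates, so no p is given. Genes of the unfolded protein response, which raises the folding capacity of the endoplasmic reticulum, were higher with a median of 0.55 over 17 genes (camera adjusted p = 3.5e-05; adjusted p = 0.592 with an estimated correlation). Among them Manf stood at 1.23 ± 0.41 and Creld2 at 1.09 ± 0.34. The integrated stress response (median 0.30, camera adjusted p = 0.0356) and nuclear-encoded oxidative phosphorylation genes (median 0.10, camera adjusted p = 0.00813) were also higher, with adjusted p = 0.687 and 0.779 with an estimated correlation. The lower lists were immediate early genes (median -0.40, camera adjusted p = 0.000196), interferon-stimulated genes (median -0.32, camera adjusted p = 0.000249), and calcium handling and ion channel genes (median -0.19, camera adjusted p = 0.00121). Lower with a larger p were fatty acid oxidation genes (median -0.07, camera adjusted p = 0.0094), heat shock genes (median -0.17, camera adjusted p = 0.0268), mitochondrially encoded genes (median -0.30, camera adjusted p = 0.0343) and desmosome genes (median -0.11, camera adjusted p = 0.0476). With an estimated correlation the lower lists had adjusted p = 0.592, 0.592, 0.286, 0.592, 0.687, 0.773 and 0.592 in the same order. Among the ion channel genes, 2 of 25 fell when adjusted over the list alone, Kcnd2 at -0.61 ± 0.12 being the one with the smallest p, and Ctnna3, a catenin of the intercalated disc, stood at -0.88 ± 0.20.

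Markers of 3 other cell types, and matrix genes, were higher as lists in Het at 4 months. The camera test passed for macrophage (median 0.27 over 12 genes, adjusted p = 0.0168), endothelial (median 0.12 over 19, adjusted p = 0.0268), fibroblast (median 0.16 over 17, adjusted p = 0.0356) and extracellular matrix genes (median 0.14 over 30, adjusted p = 0.0356). None did with an estimated correlation (adjusted p = 0.592, 0.720, 0.687 and 0.773). Within the matrix list, Lama2, the laminin alpha 2 chain, stood at -0.57 ± 0.11 and Loxl1 at 0.78 ± 0.31, and 1 gene fell when adjusted over the list alone. The lists that did not pass were sarcomere, cardiac stress, p53 targets, DNA repair, senescence-associated secretory genes, TGF-beta, glycolysis, nuclear envelope, cell cycle, NF-kappaB, Wnt and Hippo, cholesterol synthesis, pericyte and smooth muscle, adipocyte, mesothelial, atrial and Schwann cell genes, with camera adjusted p between 0.133 and 0.894. The ribosomal, unfolded protein response, immediate early, interferon-stimulated and ion channel lists passed in all 10 leave-one-out fits, and the other 10 lists did not. The matrix list was lost in 6 of the 10 fits (without WT replicates 3, 4 and 5 or Het replicates 2, 3 and 4; median 0.04 and camera adjusted p = 0.476 without WT replicate 4). Fibroblast markers were lost in 5 (without WT replicates 3, 4 and 5 or Het replicates 2 and 5; adjusted p up to 0.256). Endothelial markers were lost in 4 (without WT replicates 4 and 5 or Het replicates 1 and 5; adjusted p up to 0.343) and macrophage markers in 3 (without WT replicates 3 and 4 or Het replicate 2; adjusted p up to 0.103). The mitochondrially encoded list was lost in 5 fits (without WT replicates 2 and 3 or Het replicates 3, 4 and 5), with a median of -0.01 and adjusted p = 0.773 without WT replicate 3. With 1 surrogate variable it passed as higher (median 0.20, camera adjusted p = 0.00166). Desmosome genes were lost in 6 (without WT replicates 1, 2 and 3 or Het replicates 1, 3 and 5; adjusted p up to 0.308). The integrated stress response was lost in 4 (without WT replicates 2 and 3 or Het replicates 4 and 5; adjusted p up to 0.0861) and heat shock genes in 3 (without WT replicates 2 and 3 or Het replicate 5; adjusted p up to 0.465). Oxidative phosphorylation genes were lost in 3 (without WT replicate 1 or Het replicates 3 and 5; adjusted p up to 0.238) and fatty acid oxidation genes in 1 (without WT replicate 4; adjusted p = 0.063).

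At 9 months, 494 of 12516 tested genes differed, with 306 higher and 188 lower in Het (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 135 of the higher and 32 of the lower genes changed by over 2-fold. Genes of the cardiac stress response were among them. Ankrd1, a titin-associated stress-responsive repeat protein, rose from 2237 ± 163 to 6578 ± 1322 CPM (log2 1.56 ± 0.13, edgeR adjusted p = 7.2e-05). Nppa, atrial natriuretic peptide, rose from 49.6 ± 24.7 to 388 ± 222 CPM (log2 2.97 ± 0.40, edgeR adjusted p = 0.0018). For both, all 6 Het libraries lay above all 6 WT libraries. Sprr1a rose from 0.0576 ± 0.0478 to 2.44 ± 2.10 CPM, and the stress cytokine Gdf15 rose by 2.75 ± 0.55 (log2, SE). Among matrix and secreted genes, Lgals3, galectin 3, rose by 3.65 ± 0.55 (log2, SE), Cilp by 2.97 ± 0.47 and Comp by 2.73 ± 0.53. Tmem63c rose by 2.78 ± 0.36 and Adamts8 by 2.74 ± 0.69 from 0.455 ± 0.0945 to 3.10 ± 4.44 CPM. Adamts8 lost its call in 8 of the 12 leave-one-out fits. Metabolic genes were among the largest decreases. Acsm5, a medium-chain acyl-CoA synthetase, fell by 1.90 ± 0.37, Amy1, an amylase, by 1.51 ± 0.22 and Acot1, an acyl-CoA thioesterase, by 1.44 ± 0.31 (edgeR adjusted p from 0.00297 to 0.0202). Acot1 lost its call without Het replicate 3 (adjusted p = 0.0521). Mettl11b fell by 1.89 ± 0.33, Helt by 1.54 ± 0.29 and the chloride channel gene Clcn1 by 1.46 ± 0.24. The unadjusted p was under 0.05 for 2464 genes, with 626 expected by chance. The count was 315 without WT replicate 1, 305 without WT replicate 4, 249 without Het replicate 3, 314 without Het replicate 4 and 906 without Het replicate 6. DESeq2 called 1015, and with the mean of fibroblast markers as a covariate the count was 147, of which 100 were among the 494. Of 50 called genes selected by the naming rule, 28 lost their call with that covariate and 16 with the replicate number as a block. The fibroblast-marker level itself went with genotype (squared correlation 0.348). That covariate can thus also take out part of a genotype effect, and a lost call does not show that a gene follows fibroblast content. Over all alternatives the adjusted p reached 0.124 for Cilp, 0.266 for Comp and 0.263 for Gdf15.

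Of 32 lists tested at 9 months, 10 passed as higher and 6 as lower in Het. None passed with an estimated correlation, where 4 lists had an unadjusted p under 0.05, and 5 did by the rotation test fry. In random regroupings of the same libraries, 3 to 20 lists passed by camera, so many lists pass without the genotype labels. The cardiac stress and fetal programme rose with 10 of 17 genes higher and 0 lower (15 when adjusted over the list alone), a median of 0.81 and camera adjusted p = 5.0e-12 (adjusted p = 0.334 with an estimated correlation). Besides Ankrd1 and Nppa, Nppb, brain natriuretic peptide, rose by 1.09 ± 0.21. Of 21 sarcomere genes, which as a list did not pass (camera adjusted p = 0.702), Myh7, the slow myosin heavy chain, rose by 1.30 ± 0.34 (edgeR adjusted p = 0.0469) and Des, desmin, by 0.46 ± 0.09, and 19 did not pass. Myh7 lost its call in 9 of the 12 leave-one-out fits. Atrial myocyte markers, which include Nppa, had a median of 1.24 over 10 genes and did not pass as a list (camera adjusted p = 0.255); the median was 1.72 in libraries with Y-linked reads and -0.19 in those without. Extracellular matrix genes rose with 12 of 30 higher and 0 lower (25 when adjusted over the list alone), a median of 1.11 and camera adjusted p = 8.7e-13 (adjusted p = 0.334 with an estimated correlation). Tnc, tenascin C, rose by 2.69 ± 0.32 and Col14a1 by 1.74 ± 0.30. The TGF-beta list rose with 4 of 20 genes (6 over the list alone), a median of 0.20 and camera adjusted p = 0.0104 (adjusted p = 0.542 with an estimated correlation). Tgfb2 rose by 1.78 ± 0.28, Inhba by 1.82 ± 0.33, Ctgf by 1.39 ± 0.28 and Postn, periostin, by 1.75 ± 0.39, which lost its call in 4 of the 12 leave-one-out fits. Senescence-associated secretory genes rose with 5 of 21 (6 over the list alone), a median of 0.55 and camera adjusted p = 0.000382 (adjusted p = 0.479 with an estimated correlation). Among them Timp1, an inhibitor of matrix metalloproteinases, rose from 0.709 ± 0.161 to 4.55 ± 2.13 CPM.

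Markers of other cell types moved with these groups at 9 months. Fibroblast markers rose with 2 of 18 genes higher (9 over the list alone), Mfap5 by 1.99 ± 0.38 and Pi16 by 1.71 ± 0.33, with a median of 0.58 and camera adjusted p = 1.2e-05 (adjusted p = 0.477 with an estimated correlation). Macrophage and monocyte markers rose with 1 of 14 higher (12 over the list alone), Ctss, cathepsin S, by 1.46 ± 0.35, with a median of 1.03 and camera adjusted p = 9.2e-09 (adjusted p = 0.334 with an estimated correlation). Mesothelial markers rose with 1 of 9, the keratin gene Krt18 by 2.73 ± 0.42, with camera adjusted p = 0.0155 (adjusted p = 0.581 with an estimated correlation). Adipocyte markers fell with a median of -0.66 over 8 genes and 2 genes lower over the list alone (camera adjusted p = 0.0071; adjusted p = 0.334 with an estimated correlation). Endothelial markers had a median of -0.25 over 19 genes and did not pass (camera adjusted p = 0.0603). Ctss lost its call in 9 of the 12 leave-one-out fits (adjusted p up to 0.0773). With the mean of fibroblast markers as a covariate, 8 of the 16 lists still passed and 8 did not. The matrix median fell from 1.11 to 0.25 (camera adjusted p = 0.000812), that of the stress list from 0.81 to 0.58 (camera adjusted p = 1.3e-08) and that of macrophage markers from 1.03 to 0.42 (camera adjusted p = 0.00955), all still past the threshold. The integrated stress response, oxidative phosphorylation, fatty acid oxidation, immediate early and adipocyte lists also still passed. The calls that ended were cell cycle (median 0.77 before and -0.058 with the covariate, camera adjusted p = 0.841), senescence-associated secretory (0.55 and -0.028, adjusted p = 0.907), TGF-beta (0.20 and 0.03, adjusted p = 0.820) and mesothelial genes (1.01 and 0.0079, adjusted p = 0.841). Calls also ended for p53 target (0.16 and 0.066, adjusted p = 0.0638), calcium handling and ion channel (-0.17 and -0.014, adjusted p = 0.567) and nuclear envelope genes (-0.09 and -0.058, adjusted p = 0.155), and for fibroblast markers, which are the covariate. Mesothelial markers no longer passed without WT replicate 2 (camera adjusted p = 0.0679) or WT replicate 4 (camera adjusted p = 0.0569).

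Fatty acid oxidation and oxidative phosphorylation genes were lower as lists in Het at 9 months. Fatty acid oxidation genes fell with 9 of 29 lower and 0 higher (22 over the list alone), a median of -0.38 and camera adjusted p = 1.1e-14 (adjusted p = 0.334 with an estimated correlation). Acaa2, the thiolase of beta-oxidation, fell by 0.52 ± 0.11 and Hadh by 0.45 ± 0.10 (edgeR adjusted p from 0.0159 to 0.023). All 48 nuclear-encoded oxidative phosphorylation genes had a negative log2 fold change, with a median of -0.18 and camera adjusted p = 2.0e-11 (adjusted p = 0.436 with an estimated correlation), although none passed the gene test by itself. The 13 mitochondrially encoded genes did not pass (camera adjusted p = 0.517). Of 20 glycolysis genes Pfkp rose by 0.91 ± 0.17 and Hk1, hexokinase 1, by 0.52 ± 0.12, while the list did not pass (camera adjusted p = 0.905; 2 higher and 2 lower over the list alone). Calcium handling and ion channel genes fell with 3 of 25 lower (5 over the list alone) and camera adjusted p = 0.000389 (adjusted p = 0.436 with an estimated correlation). Kcnj11, the pore of the ATP-sensitive potassium channel, fell by 0.44 ± 0.10, Kcnd2 by 0.68 ± 0.16 and Hcn4 by 0.84 ± 0.22. Hcn4 lost its call in 9 of the 12 leave-one-out fits and Kcnj11 and Kcnd2 in 5 each (adjusted p up to 0.102), and Hadh and Hk1 in 3 each (adjusted p up to 0.0556).

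The integrated stress response rose at 9 months with 5 of 19 genes (9 over the list alone) and camera adjusted p = 1.9e-05 (adjusted p = 0.334 with an estimated correlation). Mthfd2, a mitochondrial enzyme of one-carbon metabolism, rose from 1.41 ± 0.229 to 7.37 ± 3.30 CPM, Psat1, of serine synthesis, by 1.26 ± 0.21 and Atf5 by 0.81 ± 0.17 (log2, SE). The p53 target list rose with 6 of 27 genes (7 higher and 2 lower over the list alone) and camera adjusted p = 0.00887 (adjusted p = 0.334 with an estimated correlation). Phlda3 stood at 1.75 ± 0.26, Eda2r at 0.96 ± 0.18, Gpx1 at 0.55 ± 0.10 and Aen at 0.43 ± 0.09. Cell cycle genes rose as a list (median 0.77 over 23 genes, camera adjusted p = 7.4e-05; adjusted p = 0.542 with an estimated correlation) with no member past the gene test, and did not pass with the fibroblast-marker covariate (median -0.058, camera adjusted p = 0.841). Immediate early genes, which respond to tissue dissociation among other stimuli, fell with 4 of 21 lower and 0 higher (11 lower and 1 higher over the list alone) and camera adjusted p = 1.9e-05 (adjusted p = 0.334 with an estimated correlation). Jun fell by 0.60 ± 0.10, Ier2 by 0.75 ± 0.14, Zfp36 by 1.03 ± 0.20 and Fos by 0.72 ± 0.18. Fos lost its call in 10 of the 12 leave-one-out fits (adjusted p up to 0.0913). The list of nuclear envelope and LINC complex genes, the compartment of the TMEM43 protein, fell with a median of -0.09 over 20 genes and none past the gene test (camera adjusted p = 0.0425; adjusted p = 0.334 with an estimated correlation). It no longer passed in 6 of the 12 leave-one-out fits, those without WT replicates 1, 2 and 3 or Het replicates 3, 4 and 6 (camera adjusted p from 0.0529 to 0.0769). DNA repair, interferon-stimulated, NF-kappaB, Wnt and Hippo, cholesterol synthesis, desmosome, unfolded protein response, cytosolic ribosomal, heat shock, pericyte and Schwann cell lists did not pass at 9 months, with camera adjusted p between 0.089 and 0.644. Single genes passed in these lists: 1 fell in each of the desmosome and cholesterol lists, and 1 rose in each of the Wnt and Hippo, pericyte and ribosomal lists.

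**Figure D1:**
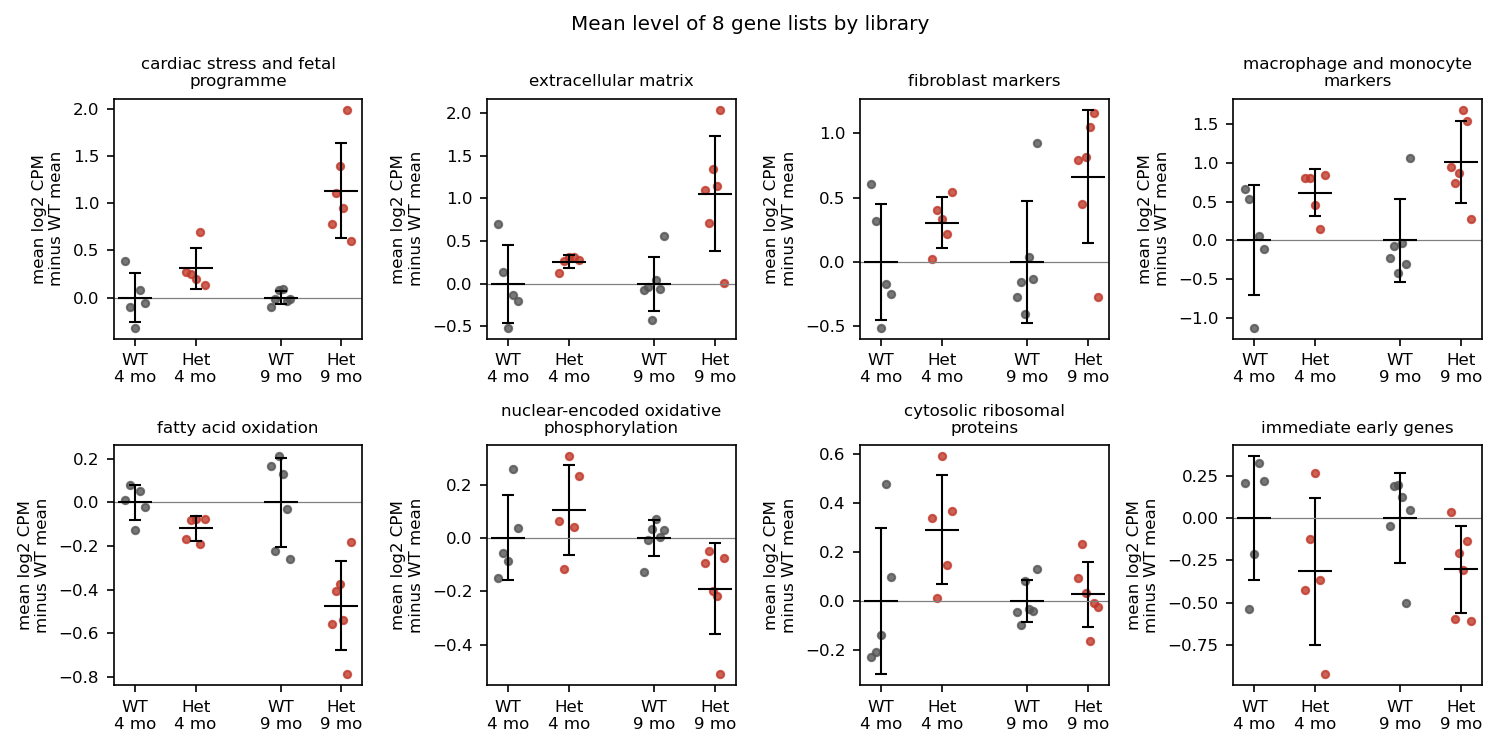
Mean log2 CPM of the genes of 8 lists in each library, minus the mean of the libraries labelled WT of the same age; points are libraries, horizontal bars are group means and error bars are SD (n = 5 per group at 4 months, n = 6 at 9 months). The stress list separates the genotypes at 9 months, and WT replicate 6 and Het replicate 6 of that age lie with the other genotype for fibroblast markers.

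The libraries with Y-linked reads and those without were also fitted apart. In edgeR fits to these smaller sets, 3 genes were called at 4 months among 3 WT and 3 Het libraries with Y-linked reads and 6 among 2 WT and 2 Het libraries without, and 17 and 671 at 9 months among 3 WT and 3 Het libraries of each kind. At 9 months the libraries with Y-linked reads were replicates 4, 5 and 6 of both genotypes, so such reads coincide with replicate number. They include WT replicate 6 and Het replicate 6, which lie with the other genotype for fibroblast markers. The 9-month contrasts between these kinds of library may rest on that. The difference in genotype effect between these kinds of library was itself tested, and 0 genes passed at either age by edgeR. At an unadjusted p under 0.05 there were 756 genes at 4 months and 1482 at 9 months, where 626 are expected by chance at each age. Lists differed by camera, though none with an estimated correlation. At 4 months the ribosomal median was 0.50 with Y-linked reads and 0.036 without (camera adjusted p of the difference = 2.5e-09), so the rise of this list was seen in the libraries with such reads. WT replicate 4, 1 of the 2 WT libraries without them, stood high for the ribosomal gene Rps14. Its log2 CPM was 5.66 against at most 4.70 in the other WT libraries. Het replicate 2 was also among the libraries without such reads. Exchanging these 2 libraries between genotypes gave medians of 0.52 for ribosomal, -0.89 for mitochondrially encoded and 0.26 for oxidative phosphorylation genes. WT replicate 3, which stood apart in genes detected, was among those with such reads. The contrasts at 4 months may therefore rest on single libraries and not on Y-linked reads. The mitochondrially encoded median was -0.78 with Y-linked reads and 0.48 without (adjusted p = 1.2e-08). That of matrix genes was 0.02 and 0.49 (adjusted p = 0.000526) and that of fibroblast markers -0.06 and 0.62 (adjusted p = 0.00475). Of the lists that passed at 4 months, oxidative phosphorylation (0.22 and -0.02, adjusted p = 1.4e-05), integrated stress response (0.64 and -0.01, adjusted p = 0.00475) and heat shock genes (-0.26 and 0.20, adjusted p = 0.000431) differed as well. At 9 months oxidative phosphorylation genes were lower in both kinds (-0.27 and -0.08, adjusted p = 5.8e-05) and fibroblast markers higher in both (0.43 and 0.88, adjusted p = 0.0291). The medians of 3 other lists had opposite signs: atrial markers (1.72 and -0.19, adjusted p = 0.0246), ribosomal protein genes (-0.10 and 0.12, adjusted p = 0.00034) and unfolded protein response genes (0.05 and -0.24, adjusted p = 0.00941).

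The genotype effect at 9 months was then compared with that at 4 months in a single model of all 22 libraries. No gene passed among 13148 tested (edgeR, Benjamini-Hochberg adjusted), 1004 had an unadjusted p under 0.05 where 657 are expected, and DESeq2 called 17. The smallest p belonged to Timp1, whose effect was higher at 9 months by 2.49 ± 0.46 (log2, SE; edgeR adjusted p = 0.200), followed by Ddah1, Rtn4, Cilp and Prkar1a in that direction. Ogdhl, at 0.13 (log2, edgeR adjusted p = 0.949) at 9 months, had a difference of -6.04 ± 1.25 (edgeR adjusted p = 0.307), and Capn11, H1f0, C2cd2 and Nenf followed in that direction. As lists, 12 differed towards a higher effect and 5 towards a lower effect at 9 months by camera, and none passed with an estimated correlation (3 lists at an unadjusted p under 0.05) or by fry. In random regroupings of the same libraries, 0 to 19 lists passed by camera. The differences included extracellular matrix (median 0.88, camera adjusted p = 9.1e-12) and cardiac stress genes (median 0.94, camera adjusted p = 5.3e-08) in the higher direction. In the lower direction they included oxidative phosphorylation (median -0.26, camera adjusted p = 6.7e-16), fatty acid oxidation (median -0.36, camera adjusted p = 2.7e-09), ribosomal protein (median -0.26, camera adjusted p = 1.0e-07) and unfolded protein response genes (median -0.65, camera adjusted p = 1.0e-05). With an estimated correlation each of these had adjusted p = 0.388, except ribosomal protein genes at adjusted p = 0.440.

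Across the 12292 genes tested at both ages, the log2 fold changes had a Pearson correlation of 0.300 and a Spearman correlation of 0.266. These values are across genes, which are not independent replicates, and the ages have separate WT libraries. Of 15 genes called at 4 months and 476 called at 9 months among them, 7 were called at both, all in the same direction, where 0.303 are expected from independent calls. Kcnv2, Alox5 and Exoc2 were among those that fell at both ages, and Ndnf, Jpt1 and Esd rose at both. Exoc2 went from 23.9 ± 2.08 to 14.9 ± 1.34 CPM at 4 months and from 25.4 ± 1.54 to 12.5 ± 1.55 CPM at 9 months, and Ndnf from 9.78 ± 2.20 to 23.9 ± 8.12 CPM and from 7.18 ± 1.42 to 22.1 ± 4.22 CPM. Of the 476 genes called at 9 months, 399 (83.8%) had the same sign at 4 months, 242 of 291 that rose and 157 of 185 that fell. In the direction of the 9-month change their median log2 fold change was 0.30 at 4 months, against 0.68 at 9 months. These genes were selected by their 9-month p, which raises the 9-month median. The 2 medians therefore do not measure a growth of the effect with age. The share with the same sign over all 12292 genes is not given here.

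**Figure D2:**
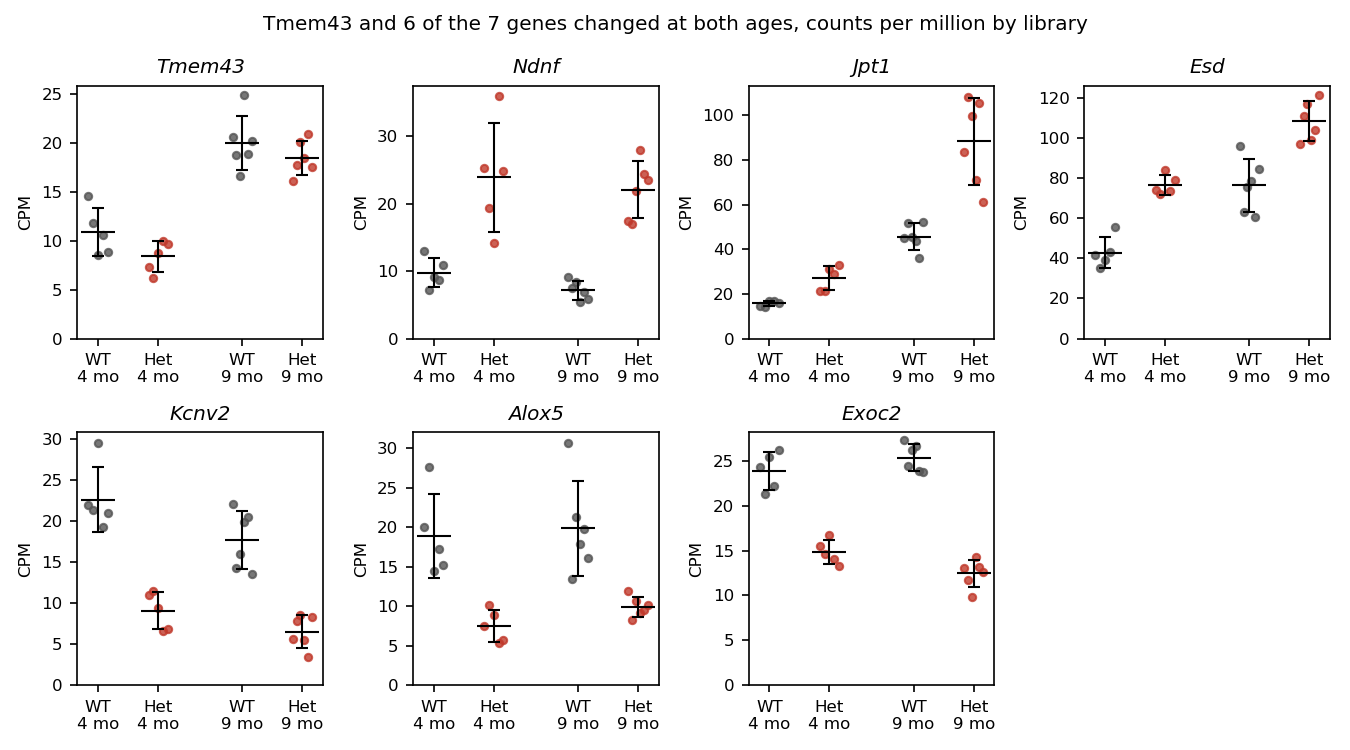
Level (CPM) of Tmem43 and of 6 of the 7 genes that changed at both ages, by library (points), with group means (horizontal bars) and SD (error bars; n = 5 per group at 4 months and n = 6 at 9 months). For each of these 6 genes the libraries labelled WT and Het do not overlap at either age, while those of Tmem43 do.

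**Figure D3:**
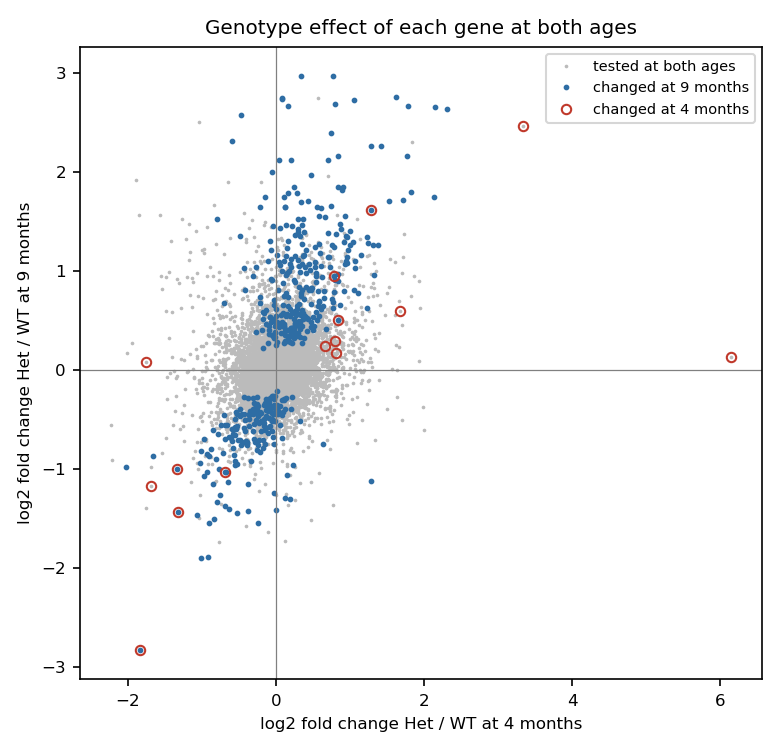
Log2 fold change of Het against WT for each of 12292 genes at 4 months (horizontal axis) and 9 months (vertical axis), with genes called at 9 months as filled points and genes called at 4 months as open circles. Of the genes called at 9 months, 83.8% have the same sign at 4 months.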

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

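The splits of the libraries were planned, except those balanced for Y-linked reads, which were added after, and all tests in this part except that of exonic length, the splits included, had their outcomes written down only after the results were seen.

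Genes of the extracellular matrix and markers of fibroblasts and macrophages were higher in Het libraries at 9 months. A lower share of myocytes would raise the markers of every other cell type alike, yet fibroblast markers rose against endothelial markers by 0.83 ± 0.18 (log2, SE; exact permutation p = 0.00649, 2-sided over 924 regroupings, n = 6 per group). More fibroblasts in an unaltered state would raise matrix genes only as much as fibroblast markers, yet matrix genes rose by a further 0.39 ± 0.14 (log2, SE; exact permutation p = 0.00649), and by 0.32 ± 0.12 without WT replicate 6 (exact permutation p = 0.0152). Both predictions hold only if myocytes give no reads to these markers and the other cell types pass the isolation alike. Neither condition was tested, so the values argue against either account as the whole cause only where both hold. With the fibroblast-marker level as a covariate the matrix median fell from 1.11 to 0.25. A fibroblast response together with a larger number of fibroblasts or macrophages, in the heart or carried through the isolation, may contribute and stays untested.

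Cardiac stress genes were higher in Het libraries at 9 months, with a median log2 fold change of 0.81. Atrial tissue carried into the preparation would lower this to under 0.5 of its value once atrial markers other than Nppa are a covariate, and the median with that covariate was 0.74 (camera adjusted p = 5.3e-12). Stress of the isolation that acted more on Het libraries would raise immediate early genes, and their median was -0.48, with 4 of 21 called lower and 0 higher. Only a rise was counted as such stress, so handling that lowers these genes was not tested. The list itself was lower in Het at both ages, so a difference in the isolation is not excluded. A response of the Het myocytes is a hypothesis that these tests leave open, and an effect of Cre, which WT mice lack, was not tested.

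Exchanging 1 library between genotypes gave more calls than the labels did. With WT replicate 4 and Het replicate 2 exchanged, edgeR called 856 genes at 4 months, 4 of them shared with the 17, and with WT replicate 6 and Het replicate 6 exchanged it called 1072 at 9 months, 199 of them shared with the 494, which points to a structure of the samples beside genotype. A swap of labels would put these libraries with the other genotype in a score from the genes called at the other age, and 0 libraries were out of place: at 4 months the WT scores reached at most -0.04 and the Het scores were at least 0.09 over 476 genes, and at 9 months the limits were -0.33 and 0.41 over 15 genes. At 9 months the exchanged split had the largest difference in mean fibroblast-marker level, since 1 of the 462 splits, itself, had a difference as large, which is consistent with a share of other cells that varies between libraries; with that level as a covariate the split called 0 genes, but this has little weight because level and exchanged group nearly coincide (squared correlation 0.890). At 4 months genes called lower after the exchange had a median exonic length 2.92 times that of genes called higher (7866 against 2691 bases), with 20 of 35 ribosomal protein genes called higher, so a difference between libraries that follows transcript length, such as in RNA quality or library preparation, may underlie it. Some lists had a smaller camera adjusted p after the exchange than by the labels. At 9 months these included matrix (median 1.31, 7.3e-19), fibroblast (1.08, 3.0e-16) and macrophage genes (1.45, 1.7e-13). At 4 months they included ribosomal (0.52, 1.1e-18) and oxidative phosphorylation genes (0.26, 1.1e-11). It was larger for others, such as cardiac stress genes at 9 months (4.1e-06). A small list p is thus not particular to the labels.

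The labels were also set against other splits of the same libraries, 100 drawn per result, the real one included. As many genes as the labels gave were called in 3 of 100 splits at 4 months (17 genes; highest other 856) and 2 of 100 at 9 months (494; highest other 1072). The labels put equal numbers of libraries with Y-linked reads in each group, and most of the drawn splits do not. Among splits that do, 3 of all 60 gave as many genes at 4 months, a share of 5%, and 2 of 100 drawn at 9 months. The share was thus under 0.05 for the genes at 9 months but not for those at 4 months. The shares given here are not adjusted over the results compared, and those of drawn splits vary with the draw. A share under 0.05 therefore does not exclude chance. For the genes with a difference between ages the real count was 0, which all 100 splits reach by construction (highest other 2), so this count says nothing about chance. The share was under 0.05 for the 15 lists at 4 months (2 of 100 splits, highest other 16, and 2 of 60 balanced splits). It was not for the 16 lists at 9 months (25 of 100 splits, highest other 20, and 25 of 100 balanced splits). The lists with a difference between ages were reached in 3 of 100 splits (17, highest other 19) but in 7 of 100 balanced ones, so the balanced share was not under 0.05. For the correlation between ages, 0.300, the share was under 0.05 in both kinds of split (2 of 100 splits, highest other 0.330, and 1 of 100 balanced splits).

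A library lay far from the rest of its group in 30 of 408 checks, where chance gives about 1 in 20, or 20.4; for 27 of the 30 the ratio of its gap to the range of the group follows each name. At 4 months these included WT replicate 3 for Ogdhl (0.755, low), Loxl1 (0.763, low) and the interferon-stimulated list (0.853, low), WT replicate 4 for Cox8b (0.824, high), Rps14 (0.777, high) and Tjp1 (0.827, low), WT replicate 5 for Klk1b22 (1, the only WT library with counts), Het replicate 1 for the matrix list (0.724, low), Het replicate 2 for the mesothelial list (0.743, low) and Het replicate 5 for the heat shock list (0.730, low). At 9 months WT replicate 6 stood high for the fibroblast (0.667), macrophage (0.736) and TGF-beta lists (0.649), Pdgfra (0.722), Adgre1 (0.778) and Krt18 (0.634), and low for Mthfd2 (0.834). Het replicate 5 stood low for the oxidative phosphorylation list (0.636), Cox7a1 (0.696), Hadh (0.633), Tnni3 (0.689) and Clcn1 (0.696). WT replicate 5 stood high for the mitochondrial share (0.629) and low for immediate early genes (0.651), and WT replicate 2 low for Bnc1 (0.741). Het replicate 6 stood low for Col14a1 (0.656) and high for neutrophil markers (0.665), at a mean log2 CPM of 5.02 against at most 1.67 in the other Het libraries. That mean covers only the tested neutrophil markers, which were fewer than 5.

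The effect of genotype on 17 lists differed between ages by camera, and none did with an estimated correlation. In order of camera adjusted p these were oxidative phosphorylation (6.7e-16, lower at 9 months), extracellular matrix (9.1e-12, higher), fatty acid oxidation (2.7e-09, lower), interferon-stimulated (7.8e-09, higher), cardiac stress (5.3e-08, higher), ribosomal protein (1.0e-07, lower), unfolded protein response (1.0e-05, lower), cell cycle (8.3e-05, higher), senescence-associated secretory (0.000361, higher), endothelial (0.00129, lower), heat shock (0.00243, higher), TGF-beta (0.00456, higher), fibroblast (0.00553, higher), atrial (0.0285, higher), desmosome (0.0368, higher), macrophage (0.0375, higher) and erythroid genes (0.0418, higher). With each of the 22 libraries left out in turn, macrophage markers were lost in 13 fits, desmosome genes in 8, atrial markers in 7 and fibroblast markers and heat shock genes in 1 each, and erythroid genes in 9 of the 18 fits that could test them. Between libraries with and without Y-linked reads the effect of genotype differed for 11 lists at 4 months and 5 at 9 months by camera, and for 0 with an estimated correlation at either age. At 4 months these were ribosomal protein, mitochondrially encoded, oxidative phosphorylation, glycolysis, heat shock, matrix, atrial, fibroblast, pericyte, integrated stress response and TGF-beta genes, and at 9 months oxidative phosphorylation, ribosomal protein, unfolded protein response, atrial and fibroblast genes. Few libraries of each kind entered these contrasts. An effect of single libraries therefore cannot be told apart from one that follows Y-linked reads.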

How the results depend on the processing

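The covariates named here were chosen only after the data were seen; the other alternatives were planned, and the planned covariate of Xist was not run because the tables lack that gene. At 4 months the count of 17 genes was 30 without a filter on low counts, 5 with a filter of 1 CPM, 3 with 1 surrogate variable, 102 by DESeq2, 31 by limma voom with sample weights, 74 with all 22 libraries in 1 model, and 11, 3 and 6 with Y-linked, fibroblast-marker and atrial-marker covariates. Leaving out each library gave 0 to 18: 0 without WT replicate 2 or Het replicate 1 (843 and 898 at an unadjusted p under 0.05), 2 without WT replicate 1, 4 without WT replicate 3, WT replicate 4 or Het replicate 5, 6 without Het replicate 3, 8 without WT replicate 5 and 9 without Het replicate 4. At 9 months the count of 494 was 776 with 1 surrogate variable, 1015 by DESeq2, 1020 by limma voom with sample weights and 147 with the fibroblast-marker covariate, and 249 to 906 with each library left out: 315 without WT replicate 1, 305 without WT replicate 4, 249 without Het replicate 3, 314 without Het replicate 4 and 906 without Het replicate 6. For the difference between ages the count of 0 was 17 by DESeq2 and 0 to 1 with each library left out, 1 being reached without WT replicate 3 at 4 months (Lrp8, named after its value was seen) or WT replicate 2 at 9 months. The 15 lists at 4 months became 9 with 1 surrogate variable, 7 with all 22 libraries in 1 model, 8 with the fibroblast-marker covariate, 0 with an estimated inter-gene correlation and 0 by fry, and 8 to 16 with each library left out (8 without WT replicate 3 or Het replicate 5). The 16 lists at 9 months became 12 with the fibroblast-marker covariate (8 of the 16 and 4 others), 0 with an estimated inter-gene correlation (4 at an unadjusted p under 0.05) and 5 by fry, and 15 to 18 with each library left out; the 17 lists with a difference between ages became 0 with an estimated inter-gene correlation and 0 by fry, and 12 to 19 with each library left out. The camera direction turned with the fibroblast-marker covariate for extracellular matrix at 4 months (median -0.00053) and for NF-kappaB (-0.22), fibroblast (-0.059) and pericyte (-0.27) genes at 9 months, the fibroblast list being the covariate itself and the pericyte median being negative before as well. With that covariate the medians of cell cycle (-0.058) and senescence-associated secretory genes (-0.028) at 9 months also passed below 0, as did that of atrial markers between ages with the atrial-marker covariate (-0.04), which they form. The direction turned with 1 surrogate variable for mitochondrially encoded (0.20, camera adjusted p = 0.00166) and heat shock genes (0.081, adjusted p = 0.698) at 4 months. It also turned for mitochondrially encoded genes between ages (-0.27, adjusted p = 0.00957). The mitochondrially encoded list thus passed at 4 months in the opposite direction with that variable and is among the 9 lists. The cause of these shifts was not tested. Tmem43 stayed from -0.54 to -0.23 at 4 months and from -0.20 to -0.04 at 9 months and never passed, and the correlation between ages stayed from 0.245 to 0.352. With the replicate number as a block, 7 genes were called at 4 months and 192 at 9 months; 0 of 5 and 3 of 6 same-numbered pairs correlated above 0.1 in their deviations, and 0 and 1 libraries correlated best with their own number, so the numbers were not taken as pairs. In simulated counts at 4 months 41.5% of genes below the median level and 96.6% of those above it were recovered when changed 2-fold, so low genes are less covered; depth itself was not varied.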

Other observations

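The tests and genes in this part were chosen after their values were seen. With the 7 genes called at both ages among them, 116 genes had an unadjusted edgeR p under 0.01 at both. By independent results 24.1 are expected, and 115 of the 116 had the same direction, 52 higher and 63 lower in Het. Genes that move together are not independent, and regroupings of the libraries were not run for this count. The value of 24.1 may therefore understate what chance gives. Dmd, dystrophin, was lower at both ages and stood at -0.91 at 4 months and -0.87 at 9 months (log2; edgeR adjusted p = 0.00726 at 9 months), Ctnna3 at -0.88 and -0.80 (adjusted p = 0.00659), the chloride channel Clcn1 at -1.07 and -1.46 (adjusted p = 0.00466), and Erbb4, a receptor for neuregulins, at -0.97 and -0.69 (adjusted p = 0.0492). Among those higher at both were Phlda3, a p53 target, at 2.13 and 1.75 (adjusted p = 0.00309), Edn3, endothelin 3, at 2.31 and 2.63 (adjusted p = 0.00899), Acta2, smooth muscle actin, at 0.94 and 1.07 (adjusted p = 0.0159), and Ucp2, a mitochondrial carrier, at 1.32 and 0.96 (adjusted p = 0.0244). None of these passed at 4 months by edgeR.

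The genes called at 4 months were also placed on chromosomes. Of the 17, 4 lie on chromosome 14, which holds 430 of the tested genes and would be expected to hold 0.584 (exact hypergeometric test, p = 0.00229, adjusted p = 0.0504 over 22 chromosomes), so the adjusted value did not pass. Within 10 Mb of Tmem43 on chromosome 6, 0 genes were called by edgeR at 4 months, where 0.167 are expected, and 5 at 9 months, where 4.97 are expected. On the whole of chromosome 6, 2 genes were called at 4 months, where 0.825 are expected, and 30 at 9 months, where 24.3 are expected. The 2 at 4 months were Ndnf and Alox5, which start at 65671590 and 116410077, outside that window, and were called at both ages.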
